A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

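Total RNA was taken from Saccharomyces cerevisiae grown in rich medium, and RNA of 50 to 100 nt was selected for sequencing, per the labels. There were 4 groups of 2 libraries, 8 libraries in all. The groups were a wild-type strain (WT) and a strain carrying a mutant of the SUMO-conjugating enzyme (ubc9-1), each untreated or treated with 100 nM rapamycin, an inhibitor of the kinase complex TORC1, for 30 minutes. Groups and replicate numbers were taken from the sample labels, and the labels do not say whether the replicates were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

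The submitters' processing notes name TopHat2 2.0.13, featureCounts 1.4.6-p3 and the genome build R64. The deposited counts are whole-number counts of aligned fragments per gene, not normalized; per the file headers, featureCounts was run on paired reads at gene level, with each alignment of a multi-mapping read counted, without use of the strand, and with no option to assign reads in overlapping genes. The deposited normalized values are CPM; each differed from CPM computed here from the counts and column totals by at most 4.4e-10. CPM were used only for an alternative test.

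The count table held 7126 features, and 6731 had a count in at least 1 library. Of the 395 features at 0 in all libraries, 358 overlap another feature; 1420 features overlap another in all. The 18S, 25S and 5.8S rRNA genes and the 8 snoRNAs hosted in introns were among those at 0, so they were not analysed here. Gene symbols and overlaps came from the R64 annotation; 5994 of the 6048 features with a locus tag in it had the same chromosome, start and end there. The 275 nuclear tRNA genes have 70 distinct sequences, and 242 of them share theirs with another tRNA gene. Because each alignment of a multi-mapping read was counted, copies with the same sequence receive the same reads, and a single tRNA, 5S or other repeated gene is uncertain. Of the nuclear tRNA genes, 10 were at 0 in all libraries. Counts were therefore also summed over anticodon families (42, of which 41 were tested).

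Library totals were 14304014 to 21061460 assigned counts. A count of 0 was read as fewer than 3 counts, which covers counting error only, and a fold against a group at 0 was computed against 3 counts summed over its libraries.

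Differences were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, on all 8 libraries with 1 coefficient per group, TMM normalization and filterByExpr (minimum count 10), which kept 6115 features. The p-values were adjusted by the Benjamini-Hochberg method within a comparison and called at 0.05. The common dispersion was 0.093, with 9.8 prior and 4 residual degrees of freedom. The 5 comparisons were rapamycin against untreated in each strain, ubc9-1 against WT without and with rapamycin, and the interaction of strain and rapamycin, which is the response in ubc9-1 minus that in WT. Log2 fold changes are edgeR estimates. Their standard errors (SE) were computed as the absolute log2 value over the square root of the F statistic, and are approximate. Shares of counts per RNA class were compared by an exact permutation test, whose smallest two-sided p for 2 against 2 libraries is 0.333.

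Lists of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 20 lists with at least 3 measured members. They held nuclear tRNA genes, families with and without introns, mitochondrial tRNAs, other RNA polymerase III transcripts, C/D and H/ACA box snoRNAs, intron-hosted and polycistronic snoRNAs, spliceosomal snRNAs, large rRNA, mitochondrial rRNA and mRNA, and mRNAs of ribosomal proteins, ribosome biogenesis, the RNA polymerase III machinery, the SUMO pathway, nitrogen catabolite repression, the general stress response, glycolysis, both mating types and auxotrophic markers. Members past the threshold were counted over all features and adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

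The features named are, per pairwise comparison, up to 6 higher and 6 lower with the largest change among those past the threshold, with a mean count of at least 50 and both libraries of a group above both of the other; for the interaction, up to 5 in each direction. SCR1, RPR1, SNR6, SNR52, the most counted 5S gene, SNR17A, LSR1, SNR19, UBC9, SMT3, RPC82 and the methionine tRNA genes were named throughout. For each list with a camera call, the rule took the 2 highest and 2 lowest members past the threshold, or the 2 most counted where none passed, and for anticodon families the 4 highest and 4 lowest. Other members of a list are given where they are called, and were chosen after their values were seen.

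The alternatives were DESeq2 size factors, total counts, TMM factors from snoRNAs, no filter, the DESeq2 1.42.0 Wald test, replicate number as a block, a fit of only the 4 libraries compared, limma on log2(CPM + 1) of the deposited CPM, and leaving out each library in turn. Leaving out both libraries with a TMM factor under 0.8 was added after the data were seen. A fit that leaves a group with 1 library pools the spread, so the lone library is assumed to vary like those of the other groups. The tests were tested on simulated data with 6115 features: at 4-fold changes the fit called 82% of changed features for rapamycin in WT, 77% for strain without drug and 38% for the interaction, and at 2-fold changes 17%, 7% and 7%. Tables and permutation tests used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures used Matplotlib 3.10.9.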

Results

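Small RNA of 50 to 100 nt was counted in 8 libraries of budding yeast. WT and ubc9-1 cells were each left untreated or given 100 nM rapamycin for 30 minutes, with 2 libraries per group. From the series title, the question is how TORC1, the kinase complex that rapamycin inhibits, acts through the SUMO modification of proteins on RNA polymerase III, the enzyme that makes tRNA and 5S rRNA. The libraries held 16173246 and 16579766 assigned counts for untreated WT, 20948512 and 21061460 for rapamycin-treated WT, 20819464 and 18145824 for untreated ubc9-1, and 14304014 and 14712987 for rapamycin-treated ubc9-1. Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom of 115, 139, 299 and 56.7 in the same order of groups. Across features, which are not independent replicates, the replicates of a group correlated with a Pearson r between 0.928 and 0.966.

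RNA polymerase III products took a large part of the assigned counts. The 5S rRNA took 34.97% ± 5.10 (SD, n = 2) of counts in untreated WT, 18.2% ± 1.46 in rapamycin-treated WT, 41.1% ± 8.94 in untreated ubc9-1 and 33.6% ± 3.31 in rapamycin-treated ubc9-1. Nuclear tRNA took 22.9% ± 2.26 and 19.9% ± 2.62 in WT without and with rapamycin, and 11.05% ± 2.85 and 8.38% ± 1.12 in ubc9-1. SnoRNA, which guides the modification and cleavage of rRNA, took 16.4% ± 2.10, 17.9% ± 2.74, 7.89% ± 0.161 and 15.5% ± 1.49 in the same order, and Ty retrotransposon features 11.97% ± 1.86, 23.0% ± 4.31, 26.3% ± 6.42 and 28.9% ± 4.29. Among nuclear tRNA counts, tD(GUC) held 39.5% ± 4.33, 32.8% ± 2.46, 40.8% ± 9.33 and 53.8% ± 3.33, and tG(GCC) 32.2% ± 5.42, 49.1% ± 2.18, 29.7% ± 12.5 and 14.4% ± 2.74. Each alignment of a shared read was counted, so genes with many copies weigh more in all these shares. The shares of nuclear tRNA in both WT groups lay above those in both ubc9-1 groups, at an exact two-sided permutation p of 0.333 with and without drug, which is the smallest that this design allows.

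**Figure D1:**
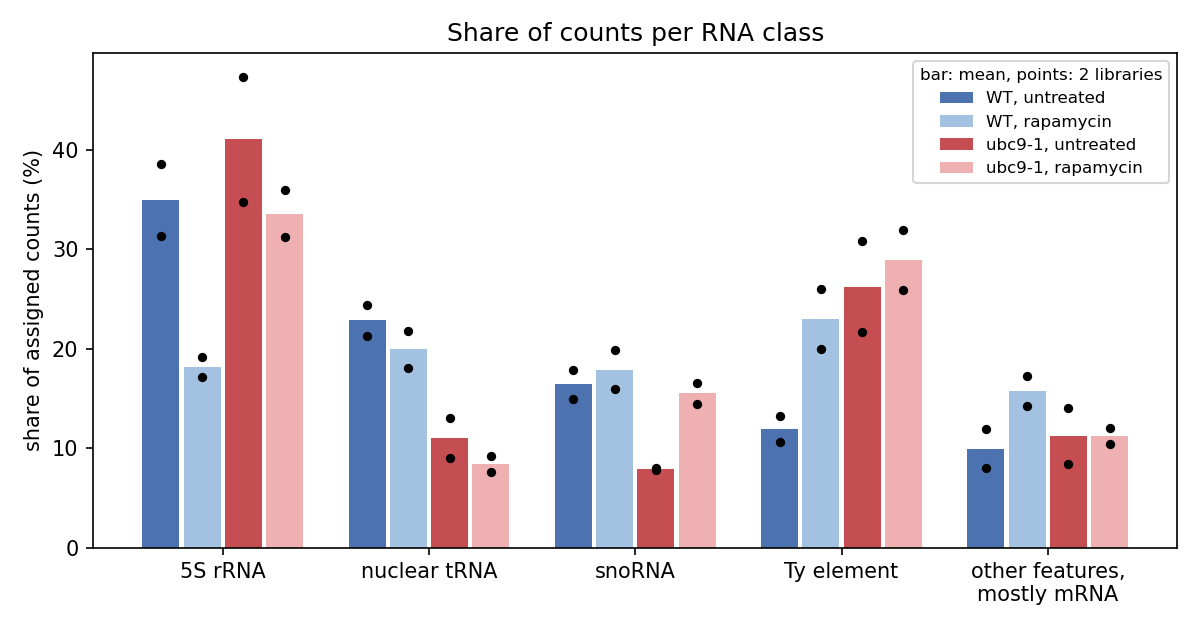
Share of assigned counts (percent, from 0) taken by 5S rRNA, nuclear tRNA, snoRNA, Ty elements and other features, mostly mRNA, in the 4 groups. Bars are means and points the 2 libraries of a group; nuclear tRNA took 22.9% in untreated WT and 11.05% in untreated ubc9-1.

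All features are compared after TMM scaling, under which the median log2 fold change of all features was 0.04 for rapamycin in WT, -0.01 for rapamycin in ubc9-1, 0.02 for strain without drug, 0 for strain with drug and -0.05 for the interaction. Scaling by total counts moved these medians to 0.52, -0.03, 0.18, -0.34 and -0.56, and scaling by snoRNAs moved them to 0.23, -0.66, 1.06, 0.21 and -0.90. The factors of the latter come from the C/D and H/ACA box snoRNAs. That scaling therefore draws the medians of snoRNA lists toward no change by construction. Every direction below is relative to the TMM median unless another scaling is named. As RNA of 50 to 100 nt was selected, counts of mRNAs and of other longer RNAs are read as counts of fragments. They need not follow the level of the whole RNA. TMM factors were 0.695 and 1.088 in untreated WT, 1.11 and 1.367 in rapamycin-treated WT, 0.719 and 1.274 in untreated ubc9-1, and 0.922 and 1.032 in rapamycin-treated ubc9-1.

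UBC9 itself (YDL064W, chromosome IV, 337487 to 338070) had 2 and 74 counts in untreated WT, 79 and 114 in rapamycin-treated WT, 307 and 554 in untreated ubc9-1, and 221 and 298 in rapamycin-treated ubc9-1. It was higher in ubc9-1 than in WT without drug, by 3.27 (log2, SE 0.645, adjusted p = 0.0198), and by 2.30 with drug (SE 0.605, adjusted p = 0.0664). Without drug the neighboring gene PEX19 was higher by 2.41 (adjusted p = 0.00227), while SYO1, on the other side, differed by -0.40 (adjusted p = 0.573). The strains also differed at auxotrophic markers. ADE2, of adenine synthesis, had 14 and 9 counts in untreated WT, 0 and 0 in rapamycin-treated WT, 189 and 302 in untreated ubc9-1, and 112 and 200 in rapamycin-treated ubc9-1. It was higher in ubc9-1 by 3.95 without drug (adjusted p = 0.00187) and at least 191-fold with it. TRP1, of tryptophan synthesis, had no count in any WT library and was at least 37.1-fold and at least 43.4-fold higher in ubc9-1 without and with drug. It overlaps YDR008C. HIS3, of histidine synthesis, was higher by 3.50 without drug and 2.48 with it (adjusted p = 0.000157 and 0.00233). LYS2, of lysine synthesis, was lower with drug, at -1.36 (adjusted p = 0.0264). These marker differences stand beside every comparison of the strains.

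Rapamycin against untreated in WT asks what TORC1 inhibition does to these RNAs in normal cells. Counts of most nuclear tRNA genes and of fragments of most mRNAs for making ribosomes fell. Counts of fragments of most mRNAs for using poor nitrogen sources rose. Of 263 measured nuclear tRNA genes, 148 fell and none rose (232 fell when adjusted over the list alone), with a median log2 fold change of -1.49 (-0.93 with scaling by total counts) and a camera adjusted p of 7.68e-33 (adjusted p = 0.612 with an estimated correlation). Of 31 measured genes under nitrogen catabolite repression, 27 rose (30 adjusted over the list alone), with a median of 3.55 (adjusted p = 6.89e-53, and 0.0748 with an estimated correlation). Of 78 measured ribosome biogenesis mRNAs, 72 fell (76 adjusted over the list alone), with a median of -2.63 (adjusted p = 9.57e-59, and 0.076 with an estimated correlation).

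Summed over anticodons, 34 of 41 tRNA families fell (20 with scaling by total counts), with a median log2 fold change of -1.70. The largest falls were in tF(GAA), at -3.31 (SE 0.478, adjusted p = 0.000125), tS(AGA) at -2.63, tK(UUU) at -2.58 and tS(GCU) at -2.56. The smallest among those that fell were tE(UUC) at -0.94, tR(CCG) at -0.97, tD(GUC) at -1.02 and tE(CUC) at -1.16. The family tG(GCC), with 16 genes, was at -0.09 (adjusted p = 0.855) and turned to 0.42 and 0.10 with scaling by total counts and by snoRNAs. The methionine family tM(CAU), which includes the initiator tRNA, fell by 1.77, and 8 of its 9 measured genes fell; tM(CAU)D was at -2.70, tM(CAU)E at -2.54, tM(CAU)P at -2.44 and tM(CAU)J1 at -2.06, and tM(CAU)O2 at -0.90 (adjusted p = 0.119). Of 57 genes in families with introns 53 fell (57 adjusted over the list alone, median -2.30), and of 206 genes in families without introns 95 fell (157 adjusted over the list alone, median -1.31, or -0.775 with scaling by total counts); both lists had an adjusted p of 0.612 or more with an estimated correlation. Among single genes, which share reads with their copies, tF(GAA)F fell by 3.55, tF(GAA)H1 by 3.51, tS(AGA)D3 by 2.92 and tS(AGA)B by 2.84, while tE(UUC)E2, tI(AAU)L1, tL(CAA)C and tL(CAA)G1 fell by 1.24, 1.21, 1.58 and 1.5. Mitochondrial tRNAs, which RNA polymerase III does not make, had a median of -0.81 (-0.395 with scaling by total counts) over 18 genes with 2 calls (0 adjusted over the list alone; adjusted p = 0.0266, and 0.878 with an estimated correlation), tD(GUC)Q at -1.65 and tS(UGA)Q2 at -1.24.

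Among other RNA polymerase III products, only copies of the 5S gene were called. The 5S gene RDN5-1 (chromosome XII, 459676 to 459796) fell by 1.5 (SE 0.443, adjusted p = 0.0282). Its counts are identical to those of RDN5-6, so a single gene copy cannot be read from them. SCR1, the RNA of the signal recognition particle, was at 0.61 (adjusted p = 0.249), RPR1, of RNase P, at -0.80 (adjusted p = 0.108), the spliceosomal SNR6 at -0.88 (adjusted p = 0.228) and the snoRNA SNR52 at -0.27. Of the 8 measured members of this list 7 had a negative value and 2 fell (median -0.84, adjusted p = 0.251). Of 24 measured mRNAs for the RNA polymerase III machinery, 7 fell and 3 rose (8 and 4 adjusted over the list alone; adjusted p = 0.238). The subunit mRNAs RPC34, RPC25, RPC37, RPC82, RPO31, RPC40 and RET1 were at -2.46, -1.81, -1.63, -1.62, -1.57, -1.56 and -1.51, and the factor mRNAs BRF1, TFC3 and TFC7 at 1.59, 1.38 and 1.12.

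The largest rises were in DAL5, an allantoate transporter, by 6.60 (SE 0.62, adjusted p = 2.2e-05), the amino acid permease GAP1, by 5.78, the regulator DAL80, by 5.44, the ammonium permease MEP2, by 5.43, and DAL7 and DAL2, of allantoin use, by 5.42 and 5.31. The proline-use genes PUT2 and PUT1 rose least among the members called, by 2.10 and 1.38. The largest falls were GFD2 at -4.99 (SE 0.647, adjusted p = 0.000177), YBL028C at -4.54, the ribosome assembly factors BRX1, DHR2 and LTV1 at -4.52, -4.28 and -3.91, and EFB1, a translation elongation factor, at -4.05. EFB1 (chromosome I, 142174 to 143160) overlaps the snoRNA snR18, which had no count in any library. Among assembly factors NIP7 was at -4.23, UTP22 at -1.45 and TIF6 at -1.28. Of 137 measured ribosomal protein mRNAs 59 fell (84 adjusted over the list alone), with a median of -0.98, or -0.56 with scaling by total counts (adjusted p = 4.19e-17, and 0.612 with an estimated correlation). RPL28 was at -2.43, RPL26A at -2.38, RPS18A at -0.95 and RPL13B at -0.94.

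Of 40 C/D box snoRNAs 6 fell (6 adjusted over the list alone), among them SNR60 at -3.01, SNR55 at -2.6, SNR69 at -1.77 and SNR87 at -1.48; the list median was -0.29 and turned to 0.19 with scaling by total counts (adjusted p = 0.0318, and 0.878 with an estimated correlation). Of 27 H/ACA box snoRNAs 2 rose (1 adjusted over the list alone), SNR30, which acts in 18S rRNA processing, by 1.93 and SNR83 by 0.95; the list median was -0.02 and turned positive with scaling by total counts and by snoRNAs. Of 17 polycistronic snoRNAs 1 fell, SNR55. The other lists had no camera call. Among 39 stress genes 8 rose, such as ALD2 by 1.57 and TPS1 by 1.49, and HSP12, GRX1 and DDR2 fell, by 1.52, 1.26 and 1.23. Of 14 SUMO pathway mRNAs AOS1, of the activating enzyme, rose by 1.59 (adjusted p = 0.0125); SMT3, which encodes SUMO, was at 0.43 and UBC9 at 0.68. Spliceosomal LSR1 and SNR19 were at 0.06 and 0.15, and SNR17A at -0.16, with no call. Of 7 auxotrophic markers HIS3 and LYS2 rose by 1.09 and 0.88 (adjusted p = 0.0262 and 0.0329), and ADE2 fell, from 14 and 9 counts to 0 and 0 (adjusted p = 0.000892), so these genes also respond within WT. Neither snRNAs, mitochondrial rRNA and mRNA (median 0.70), glycolysis mRNAs (0.22) nor mating type alpha genes had a call, and MFA2 was the only a-type gene called, at -1.63.

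In all, edgeR called 536 features higher and 712 lower in this comparison (2110 at an unadjusted p under 0.05; 587 and 849 by DESeq2). These were 583 and 265 with scaling by total counts and 266 and 363 by snoRNAs. Without replicate 1 or 2 of rapamycin-treated WT, 297 and 236 features were higher, and 323 were lower without the second. Only 17 tRNA families fell without replicate 1 of untreated WT or replicate 2 of rapamycin-treated WT, and the nuclear tRNA median was -0.85 without the former. Of 45 features named by the rule and called, 24 kept their call without any 1 library; RDN5-1, SNR55, SNR69, SNR87, RPC82, NIP7, UTP22, TIF6, PUT1, RPS18A, RPL13B, both mitochondrial tRNAs, tE(UUC)E2, tI(AAU)L1, tL(CAA)C, tL(CAA)G1 and 4 methionine tRNA genes were among the 21 that did not.

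Rapamycin against untreated in ubc9-1 asks for the same response where the SUMO-conjugating enzyme is mutated. Most nitrogen genes rose and 18 of 78 ribosome biogenesis mRNAs fell here too, no tRNA gene was called by edgeR, and 4 C/D box snoRNAs rose. Of 31 nitrogen genes 23 rose (26 adjusted over the list alone), with a median of 2.05; this list kept its camera call with an estimated correlation (adjusted p = 5.98e-87, and 0.0254 with an estimated correlation). UGA4, a transporter of the amino acid GABA, rose by 5.66 (SE 0.598, adjusted p = 0.000182), DAL5 by 5.46, MEP2 by 4.94, the urea transporter DUR3 by 4.62, GAP1 by 4.49 and DAL80 by 4.35. The asparaginase genes ASP3-1 and ASP3-2, whose counts were identical, each rose by 1.63.

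Among the falls were the ribosome assembly factors UTP9, at -2.77 (SE 0.402, adjusted p = 0.00236), SYO1 at -2.46, MRD1 at -2.19 and DHR2 at -2.09, the ribosomal protein mRNA RPL28 at -2.24, and AAH1, of adenine use, at -2.11. Of 78 ribosome biogenesis mRNAs 18 fell (57 adjusted over the list alone), with a median of -1.17 (adjusted p = 9.51e-44, and 0.113 with an estimated correlation); PUF6 was at -2.02, RLP24 at -1.95, NOP1 at -1.49 and SPB1 at -1.39. Of 137 ribosomal protein mRNAs 4 fell (4 adjusted over the list alone), with a median of -0.54 (adjusted p = 6.92e-15, and 0.641 with an estimated correlation). These were RPL28, RPL36B at -1.93, RPL16A at -1.59 and RPL18B at -1.42. Of 40 C/D box snoRNAs 4 rose (10 adjusted over the list alone), with a median of 0.65 (adjusted p = 2.44e-14, and 0.531 with an estimated correlation). SNR60 rose by 5.23 (SE 0.778, adjusted p = 0.00253), SNR58 by 3.13, SNR39B by 2.87 and SNR40 by 2.12. Polycistronic snoRNAs had a median of 0.56 with no member called (2 adjusted over the list alone; adjusted p = 0.00013, and 0.641 with an estimated correlation); SNR67 and SNR77 were at 1.07 and 1.05 (adjusted p = 0.343 and 0.274).

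None of 263 nuclear tRNA genes was called by edgeR, with 26 at an unadjusted p under 0.05 and 3 called by DESeq2. None of 41 anticodon families passed the edgeR test, with 5 at an unadjusted p under 0.05. The list median was -0.26, with a camera adjusted p of 0.00341 (adjusted p = 0.85 with an estimated correlation); the medians of families with and without introns were -0.73 and -0.25. The family tG(GCC) was at -1.80 (SE 0.502, adjusted p = 0.0992) and its gene tG(GCC)C at -1.87 (adjusted p = 0.156), tF(GAA) at -0.997 (adjusted p = 0.311) and tS(AGA) at 0.15 (adjusted p = 0.878). The 9 methionine tRNA genes ranged from -0.72 for tM(CAU)J3 to -0.29 for tM(CAU)C. RDN5-1 was at -0.43 (adjusted p = 0.88), SCR1 at 0.06, RPR1 at -0.13, SNR6 at -0.30, SNR52 at 0.26, SNR17A at 0.20, LSR1 at 0.01, SNR19 at 0.34, UBC9 at -0.29 and SMT3 at 0.08. RNA polymerase III machinery mRNAs had a median of -0.36 and no call (adjusted p = 0.0445, and 0.531 with an estimated correlation), with RPC82 at -0.97 (adjusted p = 0.317), BDP1 at -0.39 and RPO31 at -0.34. Stress genes had a median of 0.42 that turned to -0.12 with scaling by snoRNAs, and no call (adjusted p = 2.39e-05, and 0.641 with an estimated correlation). Scaling by snoRNAs moved the medians of nuclear tRNA and of families with and without introns to -0.79, -1.18 and -0.77. It moved those of ribosomal protein, ribosome biogenesis and RNA polymerase III machinery mRNAs to -1.30, -1.89 and -1.02. The medians of C/D box and polycistronic snoRNAs, which its factors are made from, moved to 0.16 and 0.08, in part by construction. With scaling by snoRNAs 9 families fell. SUMO pathway, glycolysis, mitochondrial, snRNA, mating type and marker lists had no camera call.

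In all, 51 features were higher and 40 lower by edgeR (592 at an unadjusted p under 0.05; 71 and 79 by DESeq2). These were 37 and 5 with scaling by total counts and 28 and 130 by snoRNAs. With replicate number as a block 246 features passed. Of the 51 higher, 46 were also higher in WT, against 4.47 by chance. Of the 40 lower all 40 were also lower in WT, against 4.66 by chance. The 2 comparisons share no library, but they come from 1 fit with a shared estimate of the spread. Their calls are therefore not independent, and the numbers by chance need not hold. Over the 1250 features called in either, the log2 fold changes had the same sign for 1084 (Pearson r = 0.711 across features, which are not independent replicates). Without replicate 2 of rapamycin-treated ubc9-1, 21 features were higher and 0 lower and the nuclear tRNA median was -0.07. It was -0.58 without replicate 2 of untreated ubc9-1 and -0.5 without replicate 1 of rapamycin-treated ubc9-1. It turned to 0.20 without replicate 1 of untreated ubc9-1, while without replicate 2 of untreated ubc9-1 14 features were lower and 9 families passed the test. Of 25 named features called, DAL5, DUR3, GAP1, MEP2, UGA4, SNR39B, SNR58 and SNR60 kept their call without any 1 library, and the other 17 did not.

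Ubc9-1 against WT without drug asks what the mutation does in growing cells. Some nuclear tRNA genes and C/D box snoRNAs were lower in ubc9-1, and some stress mRNAs were higher. Of 263 nuclear tRNA genes 69 were lower and none higher (162 adjusted over the list alone), with a median of -1.30, or -0.37 with scaling by snoRNAs (adjusted p = 4.76e-47, and 0.307 with an estimated correlation). Of 41 anticodon families 29 were lower, with a median of -1.42: tL(CAA) was at -2.23, tP(UGG) at -2.08, tF(GAA) at -2.07 (SE 0.455, adjusted p = 0.00192) and tL(UAA) at -2.04. With scaling by snoRNAs, 0 families passed the edgeR test. Of 57 genes in families with introns 31 were lower (54 adjusted over the list alone), with a median of -1.76, and of 206 without introns 38 were lower (107 adjusted over the list alone), with a median of -1.16; both lists had an adjusted p of 0.304 or more with an estimated correlation, and medians of -0.85 and -0.235 with scaling by snoRNAs.

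Among single tRNA genes, tP(UGG)L was at -2.67, tL(CAA)G1 at -2.51, tS(AGA)D3 at -2.47, tM(CAU)D at -2.38, tM(CAU)E at -1.70, tS(AGA)H at -1.69, tW(CCA)G1 at -1.58 and tM(CAU)J1 at -1.5. The other 6 methionine tRNA genes had no call. Of 18 mitochondrial tRNAs 3 were lower (10 adjusted over the list alone), with a median of -1.27, or -0.505 with scaling by snoRNAs (adjusted p = 5.4e-08, and 0.307 with an estimated correlation); tE(UUC)Q was at -2.58, tK(UUU)Q at -1.99 and tS(UGA)Q2 at -1.70. The 8 measured other RNA polymerase III products had no call (adjusted p = 0.384), with RDN5-1 at 0.14, SCR1 at 0.04, RPR1 at -0.17, SNR6 at -1.26 (adjusted p = 0.15) and SNR52 at -0.40; the median of -0.19 turned to 0.78 with scaling by snoRNAs.

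Of 40 C/D box snoRNAs 13 were lower (23 adjusted over the list alone), with a median of -1.12, or -0.25 with scaling by snoRNAs (adjusted p = 1.13e-21, and 0.304 with an estimated correlation). SNR60 was lower by the most, at -6.25 (SE 0.773, adjusted p = 0.00163), with 104 and 131 counts in WT and 0 and 4 in ubc9-1; it overlaps YJL047C-A. SNR58 was at -4.69, SNR39B at -4.13, SNR55 at -3.68, SNR77 at -1.62 and SNR4 at -1.47. EFB1, which overlaps snR18, was at -4.09, and tX(XXX)D at -3.59, with 702 and 117 counts in the WT libraries and an overlap with YDR340W. H/ACA box snoRNAs had a median of -0.59 that turned to 0.39 with scaling by snoRNAs, with SNR80 called at -1.76 (4 adjusted over the list alone; adjusted p = 3.49e-05, and 0.307 with an estimated correlation). Polycistronic snoRNAs had a median of -0.90 that turned to 0.02 with that scaling, with 2 lower (5 adjusted over the list alone; adjusted p = 2.02e-06, and 0.309 with an estimated correlation). Of 4 snRNAs SNR14 (U4) was lower, at -1.76 (3 adjusted over the list alone; median -1.29, or -0.28 with scaling by snoRNAs; adjusted p = 0.00141, and 0.304 with an estimated correlation), with LSR1 at -0.99, SNR19 at -1.24 and SNR17A, a snoRNA, at -0.23, none of them called.

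Of 39 stress genes 11 were higher (28 adjusted over the list alone), with a median of 1.02, or 2.04 with scaling by snoRNAs (adjusted p = 2.18e-15, and 0.304 with an estimated correlation): the membrane-protecting HSP12 by 1.68, the hexokinase HXK1 by 1.65, the mitochondrial chaperone HSP78 by 1.60, MSC1 by 1.23 and the aldehyde dehydrogenase ALD2 by 1.21. The largest rises outside the markers were YNL058C by 2.82, YBR085C-A by 2.50 and CUZ1 by 2.44. Of 31 nitrogen genes PUT2 and DAL4 were higher, by 2.06 and 1.46 (5 adjusted over the list alone), with a median of 0.505, or 1.54 with scaling by snoRNAs (adjusted p = 0.00141, and 0.35 with an estimated correlation). Ribosomal protein mRNAs had a median of -0.46 and ribosome biogenesis mRNAs of -0.69, and both turned with scaling by snoRNAs, to 0.66 and 0.35. Of the former 4 were lower (2 adjusted over the list alone; adjusted p = 4.38e-10, and 0.38 with an estimated correlation), RPS21A at -2.02, RPL28 at -1.53, RPS7A at -1.35 and RPL34A at -1.13. Of the latter 3 were lower (3 adjusted over the list alone; adjusted p = 7.92e-12, and 0.304 with an estimated correlation), NSR1 at -1.86, UTP10 at -1.21 and LTV1 at -1.16. In the machinery of RNA polymerase III TFC7 was higher by 1.66, with RPC82 at -0.37 uncalled; in the SUMO pathway UBC9 alone was called, with SMT3 at 0.67. The marker list had 3 genes higher (4 adjusted over the list alone; adjusted p = 1.61e-06, and 0.239 with an estimated correlation). Glycolysis, mitochondrial rRNA and mRNA and mating type lists had no camera call.

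Without replicate 1 of untreated WT the nuclear tRNA median was -0.70. In all, 140 features were higher and 147 lower by edgeR (1388 at an unadjusted p under 0.05; 277 and 332 by DESeq2). With scaling by total counts these were 56 and 68, and with scaling by snoRNAs 1406 and 23. Without both libraries with a TMM factor under 0.8, which are replicate 1 of each untreated group, 9 were higher and 9 lower; without any 1 of the 8 libraries 49 to 82 were higher, and 3 and 11 families were lower without replicate 1 of untreated WT and replicate 2 of untreated ubc9-1, with 38 and 32 features lower. Of 42 named features called, ADE2, TRP1, HIS3, EFB1, SNR39B, SNR58, SNR60, PUT2 and YBR085C-A kept their call without any 1 library, and the other 33, UBC9 and all tRNA genes named here among them, did not.

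Ubc9-1 against WT under rapamycin asks how the strains differ once TORC1 is inhibited. Some stress mRNAs were higher in ubc9-1. Nuclear tRNA as a list had no camera call, though its median depends on single libraries and its summed share of counts was lower in ubc9-1. Of 39 stress genes 10 were higher (27 adjusted over the list alone), with a median of 1.19 (adjusted p = 1.98e-25, and 0.226 with an estimated correlation). HSP12 was higher by 3.16 (SE 0.41, adjusted p = 0.00233), the glutaredoxin GRX1 by 2.74, GND2 by 2.50, the catalase CTT1 by 2.19, the chaperone HSP42 by 2.17, GAD1 by 2.15, RTN2 by 2.05, DDR2 by 1.99, the glycogen phosphorylase GPH1 by 1.69 and MSC1 by 1.49. Outside the lists, ARG3, of arginine synthesis, was higher by 2.99, the peroxiredoxin TSA2 by 2.83 and PEX19, next to UBC9, by 2.83, and the polyamine transporter TPO2, the vacuolar transporter VBA1 and CMR3 were lower, at -1.98, -1.94 and -1.90.

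Nuclear tRNA genes had a median of 0.01 that turned to -0.31 with scaling by total counts (adjusted p = 0.918). The 3 that were lower were copies of 1 tRNA: tG(GCC)E and tG(GCC)C at -2.82 and tG(GCC)D2 at -2.77. Of 41 families tG(GCC) was lower, at -2.71 (SE 0.519, adjusted p = 0.00315), and tT(UGU), at -1.72 (adjusted p = 0.0348). The summed share of nuclear tRNA in the counts was 8.38% in ubc9-1 against 19.9% in WT (log2 ratio -1.25, exact permutation p = 0.333). This share is on the scale of total counts, and families with many gene copies, such as tG(GCC), weigh more in it. Families with introns (median 0.01) and without (-0.02) had no camera call and turned negative and positive with scaling by total counts and by snoRNAs. The methionine tRNA genes had no call and ranged from -0.63 for tM(CAU)O2 to 0.68 for tM(CAU)P. Mitochondrial tRNAs had a median of -0.82 (-0.53 with scaling by snoRNAs) with no call (1 adjusted over the list alone; adjusted p = 0.0067, and 0.706 with an estimated correlation), with tF(GAA)Q at -1.01 and tD(GUC)Q at -0.29. RDN5-1 was at 1.22 (adjusted p = 0.162), SCR1 at -0.51, RPR1 at 0.50, SNR6 at -0.68, SNR52 at 0.13, SMT3 at 0.32 and RPC82 at 0.28.

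Of 78 ribosome biogenesis mRNAs 6 were higher (11 adjusted over the list alone), with a median of 0.59, or 0.26 with scaling by total counts (adjusted p = 3.18e-09, and 0.36 with an estimated correlation): BRX1 by 3.08, NOP8 by 2.09, LTV1 by 1.52 and NUG1 by 1.33. Of 31 nitrogen genes GDH2, a glutamate dehydrogenase, was lower, at -1.5 (12 lower and 1 higher adjusted over the list alone), and the median was -0.74 (adjusted p = 1.17e-06, and 0.344 with an estimated correlation). Of 4 snRNAs SNR14 was lower, at -1.57 (3 adjusted over the list alone; median -1.31, adjusted p = 0.000768, and 0.189 with an estimated correlation), with LSR1 at -1.04 and SNR19 at -1.05. Mitochondrial rRNA and mRNA had a median of -0.998 with no member called by edgeR over all features (10 of 10 at an unadjusted p under 0.05 and adjusted over the list alone, 4 by DESeq2; adjusted p = 1.92e-06, and 0.176 with an estimated correlation), with 15S_rRNA at -0.94 and 21S_rRNA at -0.91. H/ACA box snoRNAs had a median of -0.45 (-0.82 and -0.28 with scaling by total counts and by snoRNAs) with no call (4 adjusted over the list alone; adjusted p = 0.000217, and 0.492 with an estimated correlation); SNR30 was at -1.41 (adjusted p = 0.0723) and SNR80 at -1.22. C/D box snoRNAs had no member called by edgeR (8 at an unadjusted p under 0.05, 2 by DESeq2), with a median of -0.10 that turned positive with scaling by snoRNAs. The marker list had 3 genes higher and 1 lower (adjusted p = 7.13e-06, and 0.176 with an estimated correlation). STE2, the pheromone receptor of a cells, was lower, at -1.46 (adjusted p = 0.0285), with no alpha gene called (2 adjusted over the list alone).

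In all, 76 features were higher and 47 lower by edgeR (1089 at an unadjusted p under 0.05; 190 and 153 by DESeq2). These were 9 and 18 with scaling by total counts and 49 and 4 by snoRNAs. Without replicate 1 or 2 of rapamycin-treated WT, 4 and 2 were higher and 0 lower; without replicate 1 or 2 of rapamycin-treated ubc9-1, 15 and 14 were higher and 0 lower, and without both replicates 1 of the untreated groups 161 were higher and 118 lower. The nuclear tRNA median was 0.53 (camera adjusted p = 1.49e-07) without replicate 1 of rapamycin-treated WT, and turned to -0.30 (adjusted p = 3.39e-05) without replicate 2 of rapamycin-treated WT and to -0.28 without replicate 1 of rapamycin-treated ubc9-1. Of 23 named features called, only ADE2 kept its call without any 1 library.

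The interaction asks whether the response to rapamycin differs between the strains; a positive value means a higher, or less negative, response in ubc9-1. SNR60 was at 8.24 (SE 0.97, adjusted p = 0.00151), SNR55 at 5.33, SNR58 at 5.31 and SNR39B at 5.19. Each of these C/D box snoRNAs was lower in untreated ubc9-1 than in untreated WT; SNR60, SNR58 and SNR39B rose with rapamycin in ubc9-1. SNR55 had 918 and 124 counts in the rapamycin-treated ubc9-1 libraries. EFB1 was at 4.12, tS(AGA)D3 at 3.49, NOP8 at 2.83 and LTV1 at 2.68. On the other side, the purine-synthesis gene ADE17 was at -2.73, with 66 and 70 counts in untreated WT, 424 and 874 with rapamycin in WT, 182 and 216 in untreated ubc9-1, and 116 and 114 with rapamycin in ubc9-1. DAL4, the allantoin permease, was at -2.77.

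Of 41 anticodon families 11 had a positive interaction: tS(AGA) at 2.78 (SE 0.651, adjusted p = 0.0152), tL(UAA) at 2.32, tF(GAA) at 2.31, tL(CAA) at 2.29, tR(UCU) at 2.07, tI(UAU) at 1.88, tP(UGG) at 1.85, tA(AGC) at 1.81, tV(CAC) at 1.71, tW(CCA) at 1.59 and tP(AGG) at 1.51. The family tG(GCC) was at -1.71 (adjusted p = 0.0607). With scaling by snoRNAs only tS(AGA), at 2.18, and tG(GCC), at -2.18, passed, and with scaling by total counts tF(GAA), tL(CAA), tL(UAA), tS(AGA) and tG(GCC). Of 263 nuclear tRNA genes 1 was called (66 adjusted over the list alone), with a median of 1.28, or 0.81 and 0.59 with scaling by total counts and by snoRNAs (adjusted p = 7.46e-38, and 0.553 with an estimated correlation). These are values per gene or family. The summed share of nuclear tRNA in the counts had a log2 ratio of -0.1975 for rapamycin in WT and -0.3983 in ubc9-1 (exact permutation p = 0.667 in each). This share is on the scale of total counts, and on that scale the sum shows no smaller response in ubc9-1. The sum was not compared under TMM, where the order of the strains may differ. Each alignment of a shared read was counted, so families with many gene copies weigh more in the sum. The family tG(GCC), a large part of that sum, goes against most others, as 39 of 41 families had a positive interaction. Families with introns had no gene called by edgeR (42 at an unadjusted p under 0.05, 17 by DESeq2, 41 adjusted over the list alone; adjusted p = 3.94e-30, and 0.43 with an estimated correlation), and those without had 1 (33 adjusted over the list alone; adjusted p of 0.595 with an estimated correlation). The 9 methionine tRNA genes had no call, from 0.57 for tM(CAU)O2, which turned to -0.14 with scaling by snoRNAs, to 2.24 for tM(CAU)E (adjusted p = 0.124). RDN5-1 was at 1.07 (adjusted p = 0.47), SCR1 at -0.55, RPR1 at 0.67, SNR6 at 0.58, SNR52 at 0.53, SNR17A at 0.36, LSR1 at -0.05, SNR19 at 0.19, UBC9 at -0.97, SMT3 at -0.35 and RPC82 at 0.65, with no call.

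**Figure D2:**
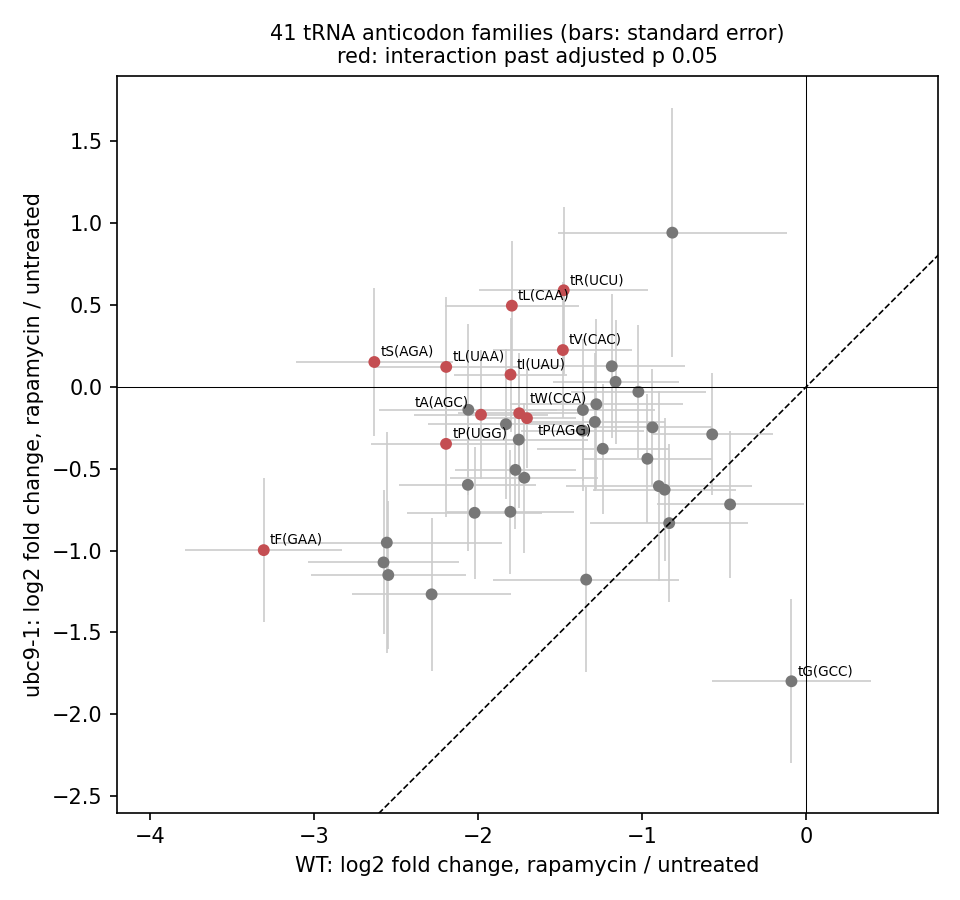
Log2 fold change of rapamycin against untreated in WT (horizontal) and in ubc9-1 (vertical) for 41 tRNA anticodon families, with bars of 1 SE, and red for the 11 families with a positive interaction. The dashed line marks equal responses; tG(GCC) lies at -0.09 in WT, which turns to 0.42 and 0.10 with scaling by total counts and snoRNAs, and at -1.80 in ubc9-1, and with scaling by snoRNAs tS(AGA) alone of the red families passes the test.

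Among the other lists, C/D box snoRNAs had 4 members higher (11 adjusted over the list alone; median 0.79, or 0.38 and 0.10 with scaling by total counts and by snoRNAs, adjusted p = 2.13e-16, and 0.43 with an estimated correlation). Ribosome biogenesis mRNAs had 2 (29 adjusted over the list alone; median 1.33, or 0.83 and 0.49 with those scalings, adjusted p = 1.03e-28, and 0.397 with an estimated correlation). Nitrogen genes had 1 lower (12 adjusted over the list alone; median -1.14, or -1.76 and -2.10 with those scalings, adjusted p = 8.38e-12, and 0.397 with an estimated correlation). Polycistronic snoRNAs, with SNR55 higher (2 adjusted over the list alone), had a median of 0.54 that turned to -0.11 with scaling by snoRNAs (adjusted p = 0.000369, and 0.72 with an estimated correlation). Mitochondrial tRNAs had a median of 0.55 that turned to -0.19 with that scaling and no call (adjusted p = 0.0177, and 0.781 with an estimated correlation), with tD(GUC)Q at 1.15 and tF(GAA)Q at -0.53. Ribosomal protein mRNAs had a median of 0.41 that turned to -0.13 with scaling by total counts and -0.51 by snoRNAs, and no call (adjusted p = 2.45e-06, and 0.748 with an estimated correlation), with RPL2A at -0.22 and RPL2B at -0.22. Mitochondrial rRNA and mRNA had a median of -0.90 (-1.66 with scaling by snoRNAs) and no call (adjusted p = 0.0163, and 0.43 with an estimated correlation). The remaining lists had no camera call. Scaling by snoRNAs takes its factors from these RNAs. The smaller or turned medians of C/D box and polycistronic snoRNAs under it therefore follow in part from its construction.

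Without replicate 1 of untreated WT the nuclear tRNA median was 0.65. In all, 8 features were higher and 2 lower by edgeR (862 at an unadjusted p under 0.05; 103 and 23 by DESeq2). These were 5 and 0 with scaling by total counts and 6 and 11 by snoRNAs. With replicate number as a block 395 features passed, among them the 10 called here. Of these 10, EFB1, SNR39B, SNR58 and SNR60 kept their call without any 1 library, and the other 6 did not. The edgeR test passed 0 families without replicate 1 of untreated WT, replicate 2 of rapamycin-treated WT or replicate 1 of rapamycin-treated ubc9-1, and 4, 25, 27 and 34 passed without replicate 2 of untreated ubc9-1, replicate 1 of rapamycin-treated WT, replicate 2 of untreated WT and replicate 1 of untreated ubc9-1.

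**Figure D3:**
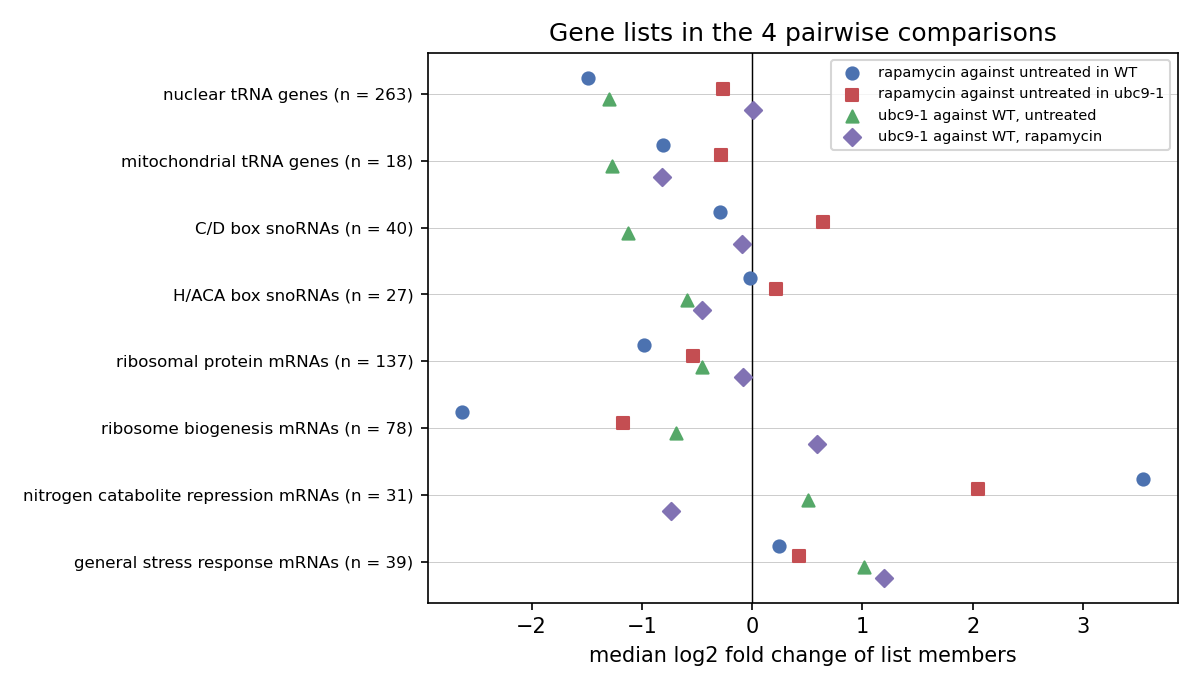
Median log2 fold change of the measured members of 8 gene lists in the 4 pairwise comparisons, relative to TMM scaling. Scaling by snoRNAs, an alternative, draws snoRNA lists toward no change by construction. Nitrogen genes lie at 3.55 and 2.05 for rapamycin in WT and ubc9-1; other scalings turn the sign of nuclear tRNA with drug between strains, C/D box snoRNAs in WT and with drug between strains, H/ACA box snoRNAs in all but the strain comparison with drug, ribosomal protein mRNAs in both strain comparisons, ribosome biogenesis mRNAs between untreated strains and stress genes in ubc9-1.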

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

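The tests of scaling, of tRNA yield in WT, of families with introns and within replicate numbers were chosen only after the result was seen. What singled out each result here is a difference between the strains in their response to rapamycin, by the edgeR interaction term for genes and families and by camera for lists.

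The genes were SNR60 at 8.24, SNR55 at 5.33, SNR58 at 5.31, SNR39B at 5.19, EFB1 at 4.12, tS(AGA)D3 at 3.49, NOP8 at 2.83, LTV1 at 2.68, ADE17 at -2.73 and DAL4 at -2.77 (log2, ubc9-1 minus WT). The anticodon families were tS(AGA) at 2.78, tL(UAA) at 2.32, tF(GAA) at 2.31, tL(CAA) at 2.29, tR(UCU) at 2.07, tI(UAU) at 1.88, tP(UGG) at 1.85, tA(AGC) at 1.81, tV(CAC) at 1.71, tW(CCA) at 1.59 and tP(AGG) at 1.51. The list medians were 1.28 for nuclear tRNA, 1.72 and 1.16 for families with and without introns, 0.79 for C/D box snoRNAs, 1.33 for ribosome biogenesis mRNAs, -0.90 for mitochondrial rRNA and mRNA and -1.14 for nitrogen genes. The medians of 0.55 for mitochondrial tRNAs and 0.54 for polycistronic snoRNAs turned to -0.19 and -0.11 with scaling by snoRNAs, and that of 0.41 for ribosomal protein mRNAs turned to -0.13 and -0.51 with scaling by total counts and by snoRNAs. With scaling by snoRNAs the medians were 0.59 for nuclear tRNA, 0.94 and 0.43 for families with and without introns, 0.10 for C/D box snoRNAs, 0.49 for ribosome biogenesis mRNAs, -1.66 for mitochondrial rRNA and mRNA and -2.10 for nitrogen genes, and of the families listed only tS(AGA) passed. Scaling by snoRNAs draws snoRNA lists toward no change by construction. Every one of the lists named here lost its call with an estimated correlation.

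Nuclear tRNA was lower after rapamycin in WT. Over the library medians, the fall was -1.545 with TMM (-2.45 standard errors), with -1.554 and -1.536 within replicate numbers. It was -1.574 (-2.43) with DESeq2 size factors, -1.042 (-3.54) with total counts and -1.358 (-3.87) with snoRNAs. At least 20 families were called lower by edgeR and none higher under each scaling, so the direction did not turn with the choice among these scalings. Its size did depend on the measure. The summed share of nuclear tRNA in the counts had a log2 ratio of -0.1975 in WT (exact permutation p = 0.667). A lower yield of tRNA-sized RNA would lower mitochondrial tRNAs as much. Over the library medians nuclear tRNA fell further by -0.404 (SD 0.182). Within replicate numbers this was -0.457 and -0.352 (SE 0.052 on 1 degree of freedom). The list medians of the edgeR fit were -1.49 for nuclear and -0.81 for mitochondrial tRNA, so the gap depends on the measure. A lower yield may account for part of the fall. Whether it does for all stays open, as the labels do not say that equal numbers pair libraries. Families with introns fell further than those without, by -0.863 (-2.24 in 10 families against -1.37 in 31, permutation p = 0.00013, Benjamini-Hochberg adjusted p = 0.00065 over 5 comparisons). The permutation is over families, which are not independent replicates, so its p does not measure the spread between libraries. A loss of newly made, unspliced tRNA could give such a difference, but so could lengths near the upper limit of selection. The action of rapamycin on RNA polymerase III stays among the open explanations.

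The median rapamycin response of nuclear tRNA genes was smaller in ubc9-1 than in WT. That of their summed share of counts, which is on the scale of total counts, was not (log2 ratio -0.1975 in WT and -0.3983 in ubc9-1, exact permutation p = 0.667 in each). The sum was not compared under TMM, where the order of the strains may differ. In the sum tG(GCC) went against most families, from 32.2% (SD 5.42) to 49.1% (SD 2.18) of nuclear tRNA counts in WT. In ubc9-1 this family went from 29.7% (SD 12.5) to 14.4% (SD 2.74), and the untreated ubc9-1 libraries differed widely. Over the library medians the difference was 1.39 (SE 0.892), or 1.56 standard errors, and with scaling by snoRNAs it was 0.64 (SE 0.496), or 1.29 standard errors, the smallest of the 4 scalings. Taken within each replicate number it was 1.125 and 1.656 (SE 0.265 on 1 degree of freedom), so a shift of whole libraries stays open: whether it cancels depends on whether equal numbers pair libraries, which the labels do not say. In every group replicate 1 had the higher nuclear tRNA median (log2 CPM). It was 7.69 against 6.71 in untreated WT and 6.13 against 5.17 in rapamycin-treated WT. In ubc9-1 it was 6.45 against 5.42 untreated and 6.02 against 5.54 with rapamycin. The main test leaves this offset in the spread between replicates. Over the library medians, the response of nuclear tRNA relative to mitochondrial tRNA differed between the strains by 0.099 (SE 0.258), or 0.384 standard errors. A lower yield of tRNA-sized RNA in untreated ubc9-1 is therefore a candidate explanation. The list medians of the edgeR interaction were apart, at 1.28 for nuclear and 0.55 for mitochondrial tRNA. How far a lower yield could account for the difference thus depends on the measure. The difference between the strains in the SUMO pathway stays open, as untested.

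The interaction was called for 4 of 40 C/D box snoRNAs, and the list lost its call with an estimated correlation (adjusted p = 0.43). If size selection did this, the interaction would follow the length of the snoRNA. Spearman's rho over 40 snoRNAs was -0.134 (permutation p = 0.406). The medians were 1.31 for 22 of at most 100 nt and 0.66 for 18 longer ones, a difference that was not tested. With 40 snoRNAs a weak dependence on length can be missed, so whether size selection contributed stays open. Without any 1 library the median of the whole list lay between 0.368 and 1.34, lowest without replicate 2 of untreated ubc9-1, so 1 library may carry a large part of it. The strain difference that the design names was not tested apart from these.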

How the results depend on the processing

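Leaving out both libraries with a TMM factor under 0.8 was chosen only after the result was seen. With 2 libraries per group at these depths, simulated 2-fold changes were called in 7% to 17% of features, so changes of that size can be missed. The simulation changed 100 of 6115 features at each fold and drew features independently. These rates need not hold where many features change or shift together. Across all alternatives, 3576 values of named features kept their side of the threshold, 635 lost the call, 86 gained it and none reversed a call. Values without a call whose sign changed are among the 3576. Unless a value below shows it, the cause was not tested.

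DESeq2 size factors left 5 features higher and 0 lower in the interaction, and 1 family between the treated strains. Scaling by total counts left 265 features lower for rapamycin in WT and 5 in ubc9-1, 56 higher and 68 lower between untreated strains, 9 and 18 between treated strains, and 5 and 0 in the interaction. It gave 20 families for rapamycin in WT, 1 in ubc9-1, 4 between treated strains and 5 in the interaction. Scaling by snoRNAs gave 266 higher and 363 lower for rapamycin in WT, 28 and 130 in ubc9-1, 1406 and 23 between untreated strains, 49 and 4 between treated strains, and 11 lower in the interaction. Its families numbered 9 for rapamycin in ubc9-1, 0 and 4 between untreated and treated strains, and 2 in the interaction. These scalings move the median of all features, by up to 1.06.

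Without a filter, 73 features were lower for rapamycin in ubc9-1, 228 higher and 237 lower between untreated strains, 155 and 102 between treated strains, and 44 and 8 in the interaction. The DESeq2 Wald test gave 79 lower for rapamycin in ubc9-1, 277 and 332 between untreated strains, 190 and 153 between treated strains, and 103 and 23 in the interaction. A fit of only the 4 libraries compared gave 52 and 94 between untreated and 152 and 121 between treated strains. Limma on the deposited CPM gave 289 lower for rapamycin in WT and 5 in ubc9-1, 54 and 94 between untreated strains, 10 higher between treated strains, and 5 and 0 in the interaction.

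The replicate number was tried as a block, although it is only a number in these labels: deviations of the libraries numbered alike correlated at 0.104 to 0.204 between groups. With the replicate block, 890 features were higher for rapamycin in WT, 96 and 150 changed in ubc9-1, 487 and 525 between untreated strains, 321 and 333 between treated strains, and 275 and 120 in the interaction, with 6, 7 and 33 families for rapamycin in ubc9-1, between treated strains and in the interaction. All 1248, 91, 287 and 123 calls of the pairwise comparisons were kept.

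Without both libraries with a TMM factor under 0.8, each untreated group has 1 library, and the lone library is assumed to vary like the others. The nuclear tRNA median for rapamycin in ubc9-1 then turned to 0.23 (adjusted p = 0.0104), 9 features were higher and 9 lower between untreated strains, 161 and 118 between treated strains, and 3 and 0 in the interaction, with 19 families for rapamycin in WT. The tRNA medians of -1.49, -0.26, -1.30 and 1.28 lost their camera call with an estimated correlation and with fry. Nuclear tRNA counts per 100 snoRNA counts were 141 and 112 in WT and 140 and 53.8 in ubc9-1, without and with drug.

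Leaving out 1 library in turn, with fewer samples in each fit, gave these ranges. For rapamycin in WT, 236 to 592 features were higher and 323 to 768 lower, 17 to 37 families passed, and the tRNA median ran from -2.05 to -0.85. In ubc9-1, 21 to 56 were higher, 0 to 53 lower, 0 to 9 families passed, and the tRNA median ran from -0.58 to 0.20, reversed without replicate 1 of untreated ubc9-1. Between untreated strains, 49 to 82 were higher, 32 to 138 lower, 3 to 40 families passed, and the tRNA median ran from -1.92 to -0.70. Between treated strains, 2 to 146 were higher, 0 to 76 lower, 0 to 3 families passed, and the tRNA median ran from -0.30 (without replicate 2 of WT) to 0.53, and was -0.28 without replicate 1 of ubc9-1. In the interaction, 4 to 11 were higher, 0 to 4 lower, 0 to 34 families passed, and the tRNA median ran from 0.65 to 1.903.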

Other observations

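The test of families with introns was chosen only after the result was seen.

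Fragments of Ty retrotransposons mostly lay on 1 side in each comparison. Of 48 Ty features, 47 had a positive log2 fold change with rapamycin in WT (median 0.44, 1 called), 46 with rapamycin in ubc9-1 (median 0.13), 43 in ubc9-1 against WT without drug (median 0.95; 0 called by edgeR, 40 at an unadjusted p under 0.05, 39 called by DESeq2) and 42 with drug (median 0.64). The interaction was negative for all 48 (median -0.30). Copies of a Ty element share reads, so these features are not independent of each other.

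The difference between families with and without introns was also tested in the other comparisons, by permutation over the 41 families, which are not independent replicates. By permutation it was -0.44 in ubc9-1 against WT without drug (p = 0.0118, Benjamini-Hochberg adjusted p = 0.0294), -0.18 for rapamycin in ubc9-1 (p = 0.361), 0.24 with drug between the strains (p = 0.327) and 0.68 in the interaction (p = 0.0197, adjusted p = 0.0328). Every difference with a p under 0.05, that for rapamycin in WT included, uses the same untreated WT libraries. These differences are therefore not separate findings, and those without untreated WT did not pass.

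The 35S rRNA features took 1.22% of counts in untreated WT, 0.636% in rapamycin-treated WT, 0.348% in untreated ubc9-1 and 0.261% in rapamycin-treated ubc9-1, and 6 of the 8 large rRNA features were at 0 in all libraries. Mitochondrial rRNA and mRNA took 1.31%, 2.73%, 1.15% and 1.13%.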
